A study of Mus musculus with 6 samples.

How the data were processed

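The data are bulk RNA-seq of sorted mouse bone marrow MSPCs, 3 control and 3 Snai2-/- libraries, grouped by the genotype in the sample titles. Per the labels' protocols, RNA was extracted with a micro-scale column kit, amplified with SMART-Seq v4 and made into Nextera XT libraries. These chemistries amplify full-length cDNA by PCR and do not mark the strand, and no molecular identifiers are mentioned. The submitters' processing notes name Trim Galore, HTSeq and edgeR 3.12.0 and the mm10 genome build, without their roles. The aligner, the annotation and the model behind the deposited p-values are not given in the sources used here.

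The file holds the authors' comparison of mutant with wildtype, 1 row per gene. Mutant was read as Snai2-/- and wildtype as control, the only 2 groups in the labels. Per the file headers, it holds a p-value, a step-up FDR (an adjusted p-value), a ratio of the group means, a signed fold change and the least-squares mean of each group. The deposited means and the column of total reads are a normalized signal, since 0 of 1285 totals are whole numbers. In all 1285 rows the total equals 3 times the sum of both means and the ratio equals their quotient, within a relative 1e-06. The fold change repeats the ratio, written as minus its reciprocal for genes that are lower. In 7 rows 1 group stands at 0.0001, a value whose origin is not given in the sources used here, and no fold is given for those genes. The deposited table holds only genes with an unadjusted p-value below 0.05 (largest listed, 0.0499). The number of genes tested, 16718, was recovered as the largest product of FDR and rank divided by p, and a step-up adjustment over that number matched the deposited FDR within 0.0225%.

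The file used here holds no library values for a test across replicates, so the fallback fixed before the data were examined was used: the authors' p and FDR are quoted, and no model was fitted here. The labels mention littermates without saying that each library came from its own animal, so the authors' p may rest on spread that is partly technical. Depth per library is unknown and no counting interval can be given. Selection at p below 0.05 also means that the listed folds are biased away from 1, most of all for low means, with a median absolute log2 ratio of 1.95 among the 322 genes with the lowest totals against 0.60 among the 321 with the highest.

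The lists (28, with 616 symbols) and the rule for named genes were fixed before the data were examined. The rule takes Snai2 and Spp1, the 10 genes with the smallest p because none passed FDR 0.05 (predicted models, Rik clones and ribosomal genes left out), and the 2 most abundant listed members of each list. Other list members and all further genes named were chosen after their values were seen. For each list with at least 3 listed members (11 lists), the median log2 ratio was compared with 100000 random lists of the same size drawn from the listed genes, two-sided, with Benjamini-Hochberg adjustment over the 11 lists. The smallest p this test can give is 2e-05. It asks whether the signed log2 ratios of a list stand apart among listed genes only. Its p therefore rests on the size of the folds, biased as stated above, as well as on direction. Members of a list vary together while random genes do not, so these p-values are smaller than a test with an estimated correlation would give, and no such correlation can be estimated without library values. Counts adjusted over the list alone use the authors' p with every member of a list taken as tested, which can only lower the count. The expected number of listed members takes 1285 of 16718 as the rate. Which genes were tested is not known, so this rate is not matched on expression.

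On simulated tables of 1285 genes, the list test called 5.5% of 110 lists with no shift, 27.3% of lists shifted by 1 and 59.1% of lists shifted by 2 on the log2 scale. The simulated lists were random genes without shared variation, and calls used an unadjusted p below 0.05. The 5.5% follows from that construction and is no false-call rate for real lists. The number of tests was recovered in 10 of 10 simulated tables. Alternatives chosen beforehand that need library values (other normalizations and tools, left-out replicates, a replicate block, set tests with a model) were not run. Those run were other FDR limits, a fold limit, a minimum mean of 1 and pseudocounts on the group means. After the data were seen, expression-matched random lists, Fisher's exact test, limits on p, a pseudocount of 1, the osteoblast list without Spp1 and a hypergeometric test of how many members were listed were added. Coordinates are 1-based from GENCODE M21 on GRCm38, the assembly that mm10 denotes, and 1247 of the 1285 symbols matched 1 gene there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.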

Results

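RNA was profiled from mesenchymal stem and progenitor cells (MSPCs) of mouse bone marrow, the stromal cells that form part of the niche of blood stem cells. About 2000 cells per library were sorted at 8 weeks of age as negative for CD45, Ter119 and CD31, surface markers of leukocytes, erythroid cells and endothelium, and positive for Nes-GFP, a green reporter driven by nestin sequences. The 6 libraries fell into 2 groups, 3 from control animals and 3 from Snai2-/- littermates. Snai2 encodes Slug, a zinc-finger transcriptional repressor of the Snail family. The values used here are a table of the authors' own comparison, with 1 mean per group, a ratio, an unadjusted p and a step-up false discovery rate (FDR) per gene. Values of single libraries, their spread and their total reads were not analysed here, so no error, sample size or depth stands beside any value. All means are on the authors' normalized scale, whose unit is not given in the sources used here.

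The comparison asks how the loss of Snai2 alters the transcriptome of these niche cells, osteopontin included. Snai2 itself (GRCm38 chromosome 16, 14705852 to 14709385, plus strand) had a mean of 636 in control and 9.20 in Snai2-/- cells in the authors' deposited table, 69.2 times lower. It ranked 1 by p and had the lowest FDR listed in the authors' deposited table, 0.0758. Spp1, which encodes the matrix protein osteopontin (chromosome 5, 104435118 to 104441050, plus strand), had a mean of 7257 in Snai2-/- and 2931 in control cells in the authors' deposited table, a ratio of 2.48. Its unadjusted p was 0.0498 and its FDR 0.65 in the authors' deposited table, where it ranked 1281 of 1285 genes by p.

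**Figure D1:**
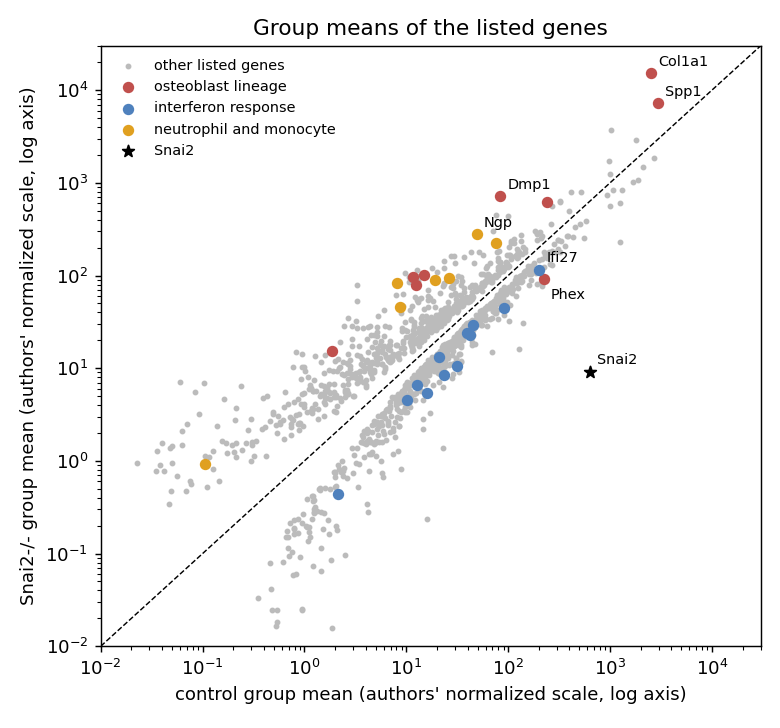
Each point is a listed gene, with its control group mean on the x axis and its Snai2-/- group mean on the y axis, both on log axes in the authors' normalized unit, and the dashed line marks equal means. 1271 genes are drawn, those with a group mean below 0.01 being left out, Snai2 lies far below the line at 636 against 9.20, and Col1a1 and Spp1 are the most abundant of the labelled genes.

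The table listed 1285 genes, 631 with a higher and 654 with a lower mean in Snai2-/- cells. None reached an FDR of 0.05 in the authors' deposited table, and 1, Snai2, reached 0.1. All 1285 had an unadjusted p below 0.05 in the authors' deposited table. The FDR values there correspond to 16718 genes tested, of which 835.9 would fall below an unadjusted p of 0.05 by chance if p were uniform. The listed genes were 1.54 times that number, and the 365 genes with p below 0.01 were 2.18 times the 167.2 expected. Of the listed genes, 590 differed at least 2-fold, 353 higher and 237 lower in Snai2-/- cells. Genes are not independent, so these ratios describe the table and carry no error.

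**Figure D2:**
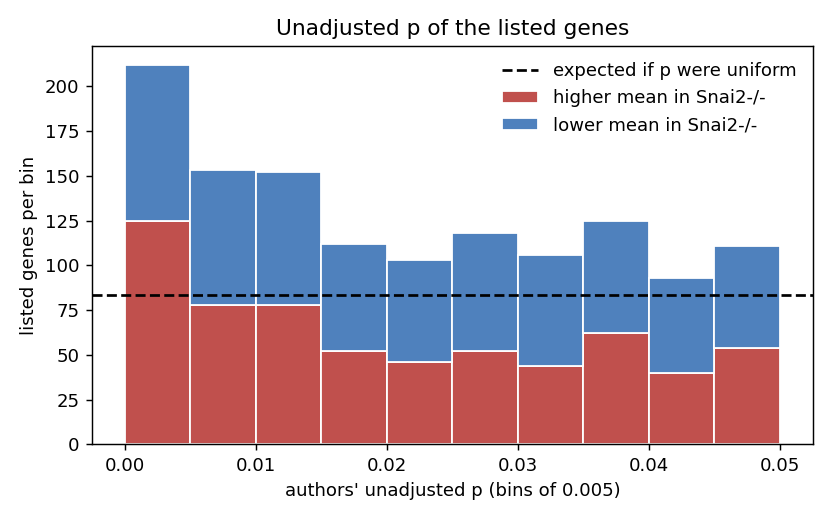
Listed genes per 0.005 of the authors' unadjusted p, split by the direction of the group means, with a dashed line at the 83.6 genes per bin expected under a uniform p. The first bin holds 212 genes and the last 111.

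After Snai2, the genes with the smallest p were mostly higher in Snai2-/- cells, though none reached an FDR of 0.05. Aldh1a3, an enzyme of retinoic acid synthesis (chromosome 7, 66390890 to 66427517), had means of 52.6 against 3.31 in the authors' deposited table, a ratio of 15.9 at FDR 0.189. The chloride channel family gene Clic5 had a ratio of 11.7 and the lipid transporter gene Abca3 a ratio of 10.1 in the authors' deposited table. Sema4d, a semaphorin, had a ratio of 4.62 there, and AI467606 a ratio of 3.88, as listed in the authors' deposited table. Slc35g1, the kinase gene Mapkapk3 and Plekhb2 had ratios of 3.24, 3.01 and 2.91 in the authors' deposited table. Col16a1, a fibril-associated collagen, was the exception, with means of 48.4 against 104.6 and a ratio of 0.463 in the authors' deposited table. Genes from Clic5 to AI467606 in that order of p shared an FDR of 0.199 in the authors' deposited table.

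Osteoblast-lineage genes were mostly higher in Snai2-/- cells among those listed. Of the 25 genes on the list, 9 were listed, 8 higher and 1 lower, with a median log2 ratio of 2.66. Runx2, Sp7, Bglap and Col1a2, also on the list, were not listed, so they had a p of 0.05 or more or were not tested. Col1a1, the main collagen of bone (chromosome 11, 94936224 to 94953042), had means of 15244 against 2546 in the authors' deposited table, a ratio of 5.99. The mineralization genes Dmp1, Ifitm5 and Alpl had ratios of 8.62, 8.17 and 2.56 in the authors' deposited table. Dlx3, Smpd3 and Col22a1 had ratios of 8.16, 6.80 and 6.33, and Phex, a regulator of phosphate and mineral, was lower at 0.413, all from the authors' deposited table. The list includes Spp1, which the title of the study names, so the direction of that gene is not independent evidence. No member passed FDR 0.05 over all genes and 0 passed adjusted over the list alone, where the lowest adjusted value was 0.0978. The median exceeded that of random lists of 9 listed genes in a two-sided permutation test of 100000 draws (adjusted p = 0.002 over the 11 lists tested), and Fisher's exact test of the split of 8 to 1 gave an adjusted p = 0.0699. The call was also lost among listed genes with p below 0.02 (median 3.03, permutation adjusted p = 0.0975, with fewer genes tested). Neutrophil and monocyte genes were also higher in the same cells, 7 of 7 listed with a median log2 ratio of 2.43.

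Chondrocyte-lineage genes that were listed were also higher, 4 of the 4 listed from 21, with a median log2 ratio of 2.80. The 4 stood against 1.61 expected for a list of that size (hypergeometric test, adjusted p = 0.226). Sox9, Acan, Col2a1 and Col10a1, also on the list, were not listed, so they had a p of 0.05 or more or were not tested. The cartilage matrix genes Col11a1, Comp and Chad had ratios of 4.36, 4.31 and 11.1 in the authors' deposited table, and Matn1 had means of 7.13 against 0.0605. The chondrocyte median passed the permutation test (adjusted p = 0.0175) and the split did not pass Fisher's exact test (adjusted p = 0.159), while 0 members passed adjusted over the list alone. Of 24 adipocyte-lineage genes 2 were listed, the lipase gene Pnpla2 and the desaturase gene Scd1, with ratios of 2.76 and 3.02 in the authors' deposited table. The 2 were close to the 1.84 expected for a list of that size and too few for the permutation test, and 0 passed adjusted over the list alone. Of 22 stem and progenitor identity genes only Ebf1, a transcription factor of marrow stroma, was listed, with a ratio of 0.58 in the authors' deposited table at FDR 0.316, and it passed adjusted over the list alone (0.0229).

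Interferon-response genes were lower in Snai2-/- cells among all 12 of the 25 that were listed, with a median log2 ratio of -0.98. Ifit1, an antiviral effector (chromosome 19, 34640871 to 34650009), had means of 8.34 against 23.3 in the authors' deposited table, a ratio of 0.358. Usp18 and Ifi44 had ratios of 0.339 and 0.338, and the transcription factor genes Irf7 and Stat2 had ratios of 0.543 and 0.611, in the authors' deposited table. Ifi27 and Rtp4, the most abundant listed members, had ratios of 0.574 and 0.49 in the authors' deposited table. Rtp4 lies within 10 Mb of Snai2. No member passed FDR 0.05 over all genes, and 12 passed adjusted over the list alone, with adjusted values from 0.0315 to 0.0462. The median lay below that of random lists in the permutation test (adjusted p = 0.0375), and Fisher's exact test of the split of 0 to 12 gave an adjusted p = 0.0052. The call was lost among listed genes with p below 0.02 (median -0.93, permutation adjusted p = 0.149). Of the 12 only Oas1a, with an unadjusted p of 0.0222 in the authors' deposited table, fell outside that limit. The call was therefore lost with nearly the whole list still tested, against a smaller pool of genes. The 12 listed genes were 6.24 times the 1.92 expected for a list of that size. Ifit3 and Oas1a have close paralogs with which reads could be shared, so their values are less certain.

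Inflammatory cytokine and NF-kB genes went both ways. Of 28 such genes 8 were listed, 4 higher and 4 lower. The chemokine genes Ccl2, Ccl7, Cxcl9 and Cxcl10 had ratios of 0.534, 0.278, 0.631 and 0.587 in the authors' deposited table. Tnfsf11, which encodes the osteoclast factor RANKL, had a ratio of 1.99 and Il6 a ratio of 3.85 in the authors' deposited table. Of the other listed chemokine genes Cxcl5 and Ccl19 were higher, with ratios of 2.05 and 1.47 in the authors' deposited table. The list's median log2 ratio of -0.05 did not stand apart in the permutation test (adjusted p = 0.901), and 0 members passed adjusted over the list alone.

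Markers of other cell types of the marrow were examined in the same table, some of them types the sort selects against. Of 18 neutrophil and monocyte genes 7 were listed and 7 were higher in Snai2-/- cells. Csf1r, Lyz2, Itgam, Mpo, Elane and S100a8, also on the list, were not listed, so the listed members do not stand for the whole list. Ngp and S100a9, granulocyte proteins, had means of 281.5 against 49.2 and 222.9 against 75.5 in the authors' deposited table. Ltf, Lcn2, Chil3 and Camp had ratios of 10.4, 5.38, 4.77 and 3.64 in the authors' deposited table, and Ly6g had means of 0.931 against 0.105. The median passed the permutation test (adjusted p = 0.0175), the split passed Fisher's exact test (adjusted p = 0.0372), and 0 members passed adjusted over the list alone. Of 15 general leukocyte genes 1, Cd48, was listed, and of 18 erythroid genes 1, Car1, with log2 ratios of 1.58 and 1.59 in the authors' deposited table. None of 18 B and T lymphocyte genes and none of 16 Schwann and neural genes was listed. Of 21 endothelial genes 3 were listed, 1 higher and 2 lower (permutation test, adjusted p = 0.22). Flt4 had a ratio of 2.09 and Vwf, the 1 listed gene of 10 on the megakaryocyte list as well, had means of 1.38 against 23.0 in the authors' deposited table. Of 13 pericyte and smooth muscle genes 2 were listed, Des and Mylk, with ratios of 0.406 and 0.727 in the authors' deposited table, and Des passed adjusted over the list alone (0.0256).

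Extracellular matrix genes divided into 4 higher and 4 lower of 8 listed from 40. The collagen VI genes Col6a1, Col6a2 and Col6a3 had ratios of 0.563, 0.488 and 0.531 in the authors' deposited table, whereas the collagenase gene Mmp13 had means of 3699 against 1033 there. Fn1, Postn and Mmp2 had ratios of 4.13, 2.97 and 2.09 in the authors' deposited table. No member passed FDR 0.05 over all genes, and 6 passed adjusted over the list alone, Fn1, Postn and Mmp13 higher and Col16a1, Col6a1 and Col6a2 lower. The median of 0.12 did not stand apart (permutation test, adjusted p = 0.901). Of 25 haematopoietic niche factors 4 were listed, 3 higher and 1 lower (permutation test, adjusted p = 0.385). Angptl4 had a ratio of 1.92 and Angpt1, a ligand of the Tie2 receptor, a ratio of 0.736 in the authors' deposited table, and the other 2 listed were Spp1 and Il6.

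**Figure D3:**
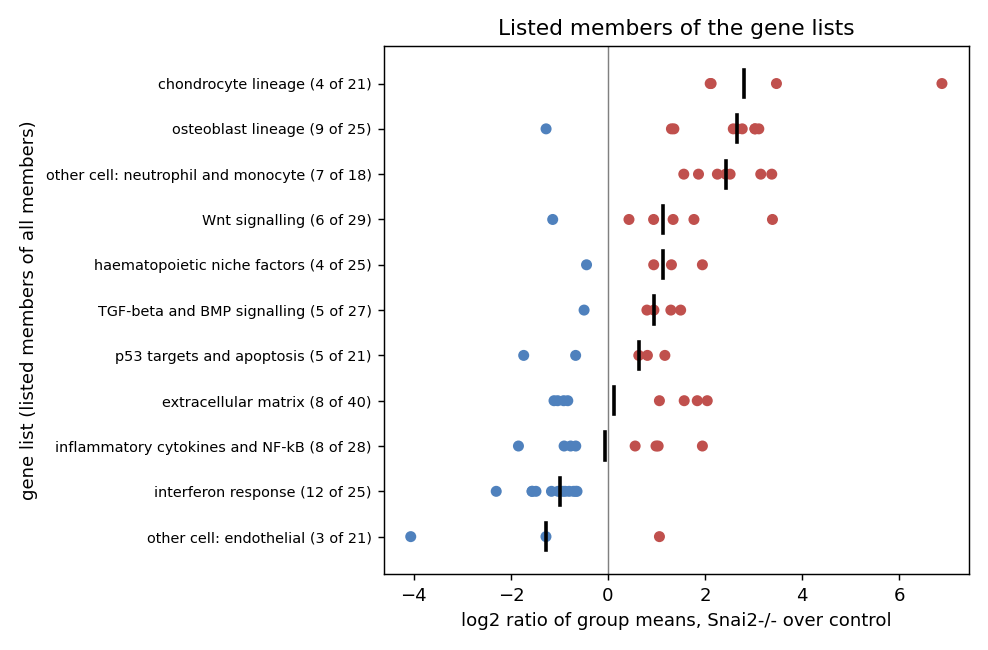
Each point is a listed member of a gene list, placed by the log2 ratio of its group means (Snai2-/- over control), and black bars mark the median of the listed members. Osteoblast members lie at 1.31 or above except Phex at -1.28, all 12 interferon-response members lie between -2.30 and -0.64, and all 7 neutrophil and monocyte members lie between 1.56 and 3.38.

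Among the signalling and growth lists, the Wnt, TGF-beta and BMP, and p53 lists had enough listed genes to test. Their median log2 ratios did not stand apart in the permutation test. Of 29 Wnt genes 6 were listed, 5 higher and 1 lower (permutation test, adjusted p = 0.297), among them the inhibitor Wif1 with a ratio of 1.92 and Ctnnb1 with 1.35 in the authors' deposited table. Of 27 TGF-beta and BMP genes 5 were listed, 4 higher and 1 lower (permutation test, p = 0.302, adjusted p = 0.415), with ratios of 1.74 for Id3 and 0.711 for the receptor gene Tgfbr2 in the authors' deposited table. Of 21 p53 and apoptosis genes 5 were listed, 3 higher and 2 lower (permutation test, adjusted p = 0.682). Cdkn1a, a cell-cycle inhibitor, had a ratio of 2.25 and Bid 1.55 in the authors' deposited table, and Cdkn1a passed adjusted over the list alone (0.038). Of 13 osteopontin receptor and integrin genes 2 were listed, Cd44 with a ratio of 1.61 and Itga6 with 0.158 in the authors' deposited table. Of 24 epithelial-mesenchymal transition genes 2 were listed, Snai2 and the tight-junction gene Tjp1, the latter with a ratio of 1.67 in the authors' deposited table. Of 31 proliferation genes 2 were listed, Kif20a and Tyms, with ratios of 2.45 and 1.69 in the authors' deposited table. The Notch list of 17 held 1 listed gene, Hey1 (ratio 1.51), the hypoxia and glycolysis list of 25 held 1, Pkm (1.57), and the ribosomal protein list of 34 held 1, Rpl4 (1.25), in the authors' deposited table. None of the 32 oxidative phosphorylation, 31 stress and immediate-early and 13 mitochondrially encoded genes was listed. A gene outside the list had either an unadjusted p of 0.05 or more or was not tested, and the 2 cases cannot be separated here.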

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

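Fisher's exact test, matched random lists, limits on p, a pseudocount of 1 and the osteoblast list without Spp1 were chosen after seeing the data. No gene passed FDR 0.05. FDR 0.01, an added absolute log2 ratio of at least 1 or a minimum mean of 1 could only leave that count at 0, since no FDR was recomputed. FDR 0.1 admitted 1 gene, Snai2 (log2 ratio -6.11). Of the 1285 listed genes, 590 had an absolute log2 ratio of at least 1 and 365 an unadjusted p below 0.01. The share higher in Snai2-/- cells moved from 49.1% to 59.8% and 55.6% under those limits. The osteoblast list (median 2.66) kept its direction throughout but lost its call by Fisher's exact test of the split (adjusted p = 0.0699) and among genes with p below 0.02 (median 3.03, permutation adjusted p = 0.0975, with fewer genes tested). The chondrocyte list (median 2.80) lost its call by Fisher's exact test (adjusted p = 0.159), and the interferon list among genes with p below 0.02 (median -0.93, permutation adjusted p = 0.149). Without Spp1 the osteoblast median was 2.71 (permutation adjusted p = 0.0033). The neutrophil and monocyte list kept its call in the alternatives run on it, but it and the chondrocyte list had too few members with p below 0.02 to be tested there. In 67 of the 72 comparisons of a list with an alternative, direction and side of the threshold were as first reported. Many of these could hardly change, being pseudocounts on the same means or lists not called at first, so that count is no measure of stability. The 4 losses of a call came from Fisher's exact test or the limit on p. The p53 list, not called in either case, changed sign among genes with p below 0.02 (median 0.64 to -0.0155, with fewer genes tested). No paired analysis was possible because the deposited values are group means, so neither a replicate block nor left-out libraries, and no other splits of the 6 libraries, could be examined. Other normalizations, filters and count models (edgeR, DESeq2, voom) and set tests with an estimated correlation (camera, fry) were not run for that reason. With 1 mean per group, whether 1 library decides any value is open for every gene named.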

Other observations

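Chosen only after the data were seen were the tests of symbol families, of transcript length between directions, of list size, of read composition, of progenitor genes and of a second neutrophil list, as were all genes named here outside the fixed lists. These are single genes picked by hand, none at FDR 0.05 in the authors' deposited table, and they stand for no group. The phosphatase gene Phospho1 had a ratio of 8.74, the growth factor gene Bmp3 9.57, the vitamin D receptor gene Vdr 4.32, Panx3 4.08, Enpp6 4.06 and the secretory kinase gene Fam20c 3.93 in the authors' deposited table. Igf2, a fetal growth factor, had a ratio of 8.93 there, and the gap-junction gene Gja1 had means of 2901 against 1803 in the authors' deposited table. Among lower genes, complement C3 had means of 232.1 against 1254 and C1ra a ratio of 0.562 in the authors' deposited table. Enpp2, which encodes autotaxin, had a ratio of 0.224, Ptges, an enzyme of prostaglandin E synthesis, 0.276, and Cxcl16 0.497 in the authors' deposited table. Clu, Agt and Chrdl1 had ratios of 0.681, 0.699 and 0.607 in the authors' deposited table. Ifi204, Ifi203 and Iigp1 had ratios of 0.41, 0.541 and 0.61, and the histocompatibility genes H2-DMb1, H2-Q5 and H2-T22 ratios of 0.566, 0.66 and 0.698, in the authors' deposited table. H2-Q5 is annotated as a polymorphic pseudogene, and whether these genes share reads with paralogs was not tested.

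A count of symbol families with at least 6 listed members, made after the data were seen, covered 12 families. Zinc-finger genes named Zfp were listed 21 times, 3 higher and 18 lower (Fisher's exact test against the other listed genes, adjusted p = 0.0085). Predicted models named Gm were listed 36 times, 7 higher and 29 lower (Fisher's exact test, adjusted p = 0.00335). The 6 listed Eif translation factor genes were all higher and missed the threshold (Fisher's exact test, adjusted p = 0.0554). Listed genes with a higher mean had shorter transcripts than those with a lower mean, with a median of 3094 against 3911 bases over 616 and 633 genes (10000 permutations of the direction, p = 0.0002, the smallest they can give). GC content differed by -0.40 percentage points (permutation p = 0.37). Length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. Both permutations took genes as independent, so their p-values do not measure spread between libraries. By a hypergeometric test over 28 lists, the interferon list had more members listed than genes listed independently would give (exact test, adjusted p = 2.3e-06). So did the osteoblast (0.000841), neutrophil and monocyte (0.00217) and inflammatory lists (0.00644), with the extracellular matrix list short of the threshold (0.0561). Members of a list vary together, so these p-values are smaller than a test with an estimated correlation would give. Which genes were tested is unknown, so expression was not matched.

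The first pattern is that interferon-response genes were lower in 12 of 12 listed cases. Random lists matched on transcript length and GC content reached such a median with a two-sided permutation p = 0.0128, which argues against those properties as the whole cause. Abundant transcripts such as Col1a1 taking reads would lower all other genes alike. This list lay below listed genes matched on mean (permutation adjusted p = 0.0039). That value was already seen and replaced a test on the share of lower genes, 50.9%, once that was known. The matched genes were themselves selected at p below 0.05 in both directions, so they do not show a shift common to all genes. The comparison therefore cannot decide on that cause. The median p of the list was at or above that of 14.5% of lists matched on fold and mean, so neither a difference carried by a few libraries nor one present in all of them is excluded. A lower interferon tone in Snai2-/- cells, or an exposure shared by the control animals, may each account for it and neither was tested.

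Higher osteoblast-lineage genes in Snai2-/- cells form the second pattern. Matched for transcript length and GC content, random lists reached its median with a permutation p = 0.00048, which argues against these properties. Its median p was at or above that of 94.4% of lists matched on fold and mean, just short of the 95% set for a difference carried by a few libraries, so that stays open. A larger share of osteoblast-lineage cells among the sorted cells could give the same values as a change within each cell. Only 1 of the progenitor identity genes was listed as lower, and unlisted genes decide nothing, so these cannot be told apart.

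Neutrophil and monocyte genes, higher in 7 of 7 listed cases after a sort against CD45, form the third pattern. Their median p was at or above that of 98.3% of lists matched on fold and mean. A difference carried by a few libraries would give this, but so would wide spread across all libraries. Without library values the p-values cannot tell these apart, and genes in the matched lists do not vary together as members of this list may. RNA or cells of granulocytes left after the sort is a candidate source, first set against the 7 genes themselves, which met its limit but had raised the question, so that test was replaced. On a second list of 71 neutrophil genes, drawn up when values of some were known, 16 were listed, against 5.46 expected for its size. Of the 16, 75% were higher, short of the 80% set for that source and above the share that would exclude it. The 12 higher ones included Srgn and Lrg1, with ratios of 5.92 and 6.07 in the authors' deposited table, and the 4 lower ones were Lcp2, Tlr2, Fyb and Tlr4, at 0.321, 0.654, 0.662 and 0.676, and how specific each is to neutrophils was not tested, so carry-over stays open.

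Sequence carried along with the targeted allele, or a local effect of it, could change genes beside Snai2. Within 10 Mb on either side, 15 of 221 protein-coding genes were listed (6.79%), 8 higher and 7 lower, against a median of 5.41% around other genes. The share around Snai2 was at or above that of 73.9% of such windows. Within 5 Mb, 10 of 134 such genes were listed (7.46%), 7 higher and 3 lower, against a median of 5.21%. That share was at or above that of 80.05% of windows of that size. Both shares lay above the median without being extreme among windows, so a small local excess is neither shown nor excluded. Single neighbours may still be affected.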
